A study of Homo sapiens with 9 samples.

How the data were processed

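Clariom S expression arrays of SW480 cells were used: 3 of cells given the water vehicle, 3 of cells given sulforaphane and 3 of cells given sulforaphene, both at 25 µmol/l for 48 h. Groups, dose and time were read from the sample labels, and 0 sample columns were left unmapped. The values were taken as deposited: log2 signals, summarised by the authors to 1 value per probe set and array. MAS5 is named per the submitters' processing notes, without a version or the role it had, and the normalization between arrays is not stated. The base of the logarithm was inferred from the values, whose maximum as a power of 2 lies in the range of an array scanner. No further normalization, filter or batch correction was applied before the main test. Detection calls and background signals are not given in the sources used here. The culture origin of the replicates is not stated.

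Of 21448 probe sets, 17709 carried exactly 1 gene symbol through a gene identifier looked up in the gene table of GRCh38.p14, and 3739 stayed unnamed here. The named ones stand for 17687 genes, 20 of them with more than 1 probe set. All probe sets were tested. Array medians, interquartile ranges and Pearson's r of each pair of arrays were computed over all probe sets. Gene span, the distance from the start to the end of a gene in that table, was set against the log2 change by Spearman's rho.

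Each comparison (sulforaphane against control, sulforaphene against control and sulforaphene against sulforaphane) was a contrast of 1 linear model over all 9 arrays, fitted with limma 3.58.1 in R 4.3.3. Its moderated t-tests were adjusted over all probe sets by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. A second count took only calls of at least 2-fold. Intervals are 95% intervals of the same model. For each comparison the probe sets without overlap between the groups were counted beside the 10% that chance gives for 3 against 3 arrays.

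A set of 29 gene lists (582 genes, 528 measured) was written from general knowledge. They held NRF2 targets, metallothioneins, heat shock chaperones, ATF4 and CHOP targets, ER chaperones and degradation factors, p53 targets, G2/M genes, G1/S and replication genes, replication-dependent histones, and pro-apoptotic and anti-apoptotic genes. Further lists held WNT targets, cholesterol synthesis and uptake genes, glycolysis and hypoxia genes, NF-kB and inflammatory genes, immediate early genes, tubulins, proteasome subunits, autophagy and lysosome genes and epithelial-mesenchymal transition genes. The remaining ones held epithelial junction and keratin genes, intestinal differentiation genes, genes of the aryl hydrocarbon receptor and xenobiotic metabolism, interferon-stimulated genes, oxidative phosphorylation genes, ribosome biogenesis genes, and fibroblast, leukocyte and endothelial markers. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 29 lists of each comparison. The same test with a correlation estimated for each list is given beside every list that passed with all 9 arrays, and for those that passed only without control replicate 2 from the same fit. It was not run in the other settings. A list can lose its call with an estimated correlation that is no larger than the preset one. Such a loss therefore does not by itself measure correlation between genes. Members were also counted with p-values adjusted over the list alone.

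The groups, tests, lists, settings and genes to be named were fixed before the data were examined. Named genes are the 8 risen and 8 fallen genes of largest change per comparison without overlap between the groups, up to 4 members of each list by lowest p, and 12 genes fixed by name. These are HMOX1, NQO1, GCLM, SRXN1, CDKN1A, DDIT3, ATF3, CCNB1, MKI67, TUBB2A, HSPA1A and MT2A. The likeness of the 2 responses was measured by Pearson's r and the covariance of the log2 changes across genes. It was set against 100 simulations of unchanged groups that share the 3 controls.

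Other settings fixed in advance were quantile normalization, centring on the array median, leaving out the dimmest 33% of probe sets, a variance prior with trend and robust estimation, a fit of only the 6 arrays compared, the replicate number as a block, array weights, and leaving out each replicate. Pseudocounts, planned for linear values, were not run because the values are logarithms. Added after the data were seen were leaving each control out of the comparison between compounds and averaging sulforaphane replicates 2 and 3. Also added then were quantile normalization and estimated correlations without control replicate 2, list tests on 6 arrays, and random lists matched on gene span and mean level. Whether the replicate numbers pair the arrays was checked from the correlations of deviations from the group means, and no block was used in the main model.

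The steps were tested on simulated data in which arrays were drawn around the control means with the noise of each probe set and array, and 200 probe sets were shifted. Shifts of 2 log2 units were recovered in 85%, 78% and 75% of cases and shifts of 1 in 28%, 42% and 38% (in the order of the comparisons above), with 0 other probe sets called. A list shifted by 0.5 was called in each comparison, and 0 other lists were. Noise was drawn independently for each probe set, so false list calls from genes that vary together could not arise in this simulation. In the real arrays estimated list correlations reached 0.883, for proteasome subunits. The number of arrays limits the precision of every value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.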

Results

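Expression was profiled on 9 Clariom S arrays of SW480 cells, an established human colon adenocarcinoma line with a truncated APC gene. The cells had been kept for 48 h with sulforaphane (3 arrays), with sulforaphene (3 arrays) or with the water used as vehicle (3 control arrays). Both compounds are isothiocyanates of cruciferous plants and were given at 25 µmol/l. They share the same skeleton, and sulforaphene carries a carbon-carbon double bond in its side chain that sulforaphane lacks. Values are log2 signals of 21448 probe sets and ran from 1.71 to 13.38. Array medians lay between 5.05 and 5.20. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.242. The culture origin of the replicates is not stated, so the p-values measure only the spread between these samples, which may be technical.

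The 6 treated arrays resembled each other closely. Across probe sets, which are not independent replicates, Pearson's r was 0.987 to 0.988 within the sulforaphene group and 0.985 to 0.993 within the sulforaphane group. Between arrays of different compounds it was 0.982 to 0.983. Control replicates 1 and 3 correlated at r = 0.978, whereas control replicate 2 correlated with them at only 0.890 to 0.901. Its interquartile range was 2.20 log2 units, against 2.63 or more on the other 8 arrays. Its r with treated arrays was 0.775 to 0.803, against 0.917 to 0.933 for the other controls. Sulforaphane replicates 2 and 3 were the closest pair (r = 0.993, SD of their difference 0.217).

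**Figure D1:**
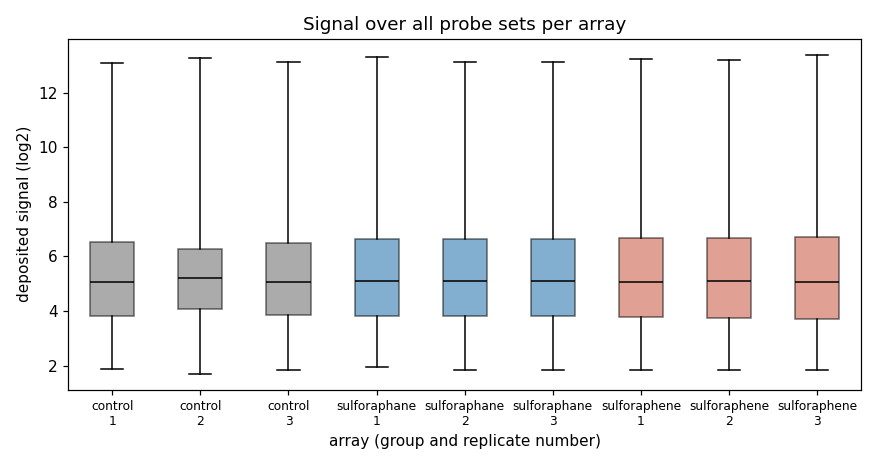
Distribution of log2 signal over all probe sets for each of the 9 arrays, as boxes from the lower to the upper quartile with whiskers to the lowest and highest value. Control replicate 2 has the narrowest box, 2.20 log2 units.

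The first comparison asked what sulforaphane does to transcript levels in these cells. ATF3, a transcription factor induced by cellular stress, stood at 10.22 ± 0.0414 log2 units with sulforaphane and 5.371 ± 0.406 in controls (mean ± SD, n = 3 each), a 28.8-fold rise. SLC7A11, the cystine importer that feeds glutathione synthesis, rose 27.8-fold (log2 change 4.80, SE 0.177, limma adjusted p = 3.01e-08). The interferon-induced gene IFI6 was 10.9-fold lower (7.708 ± 0.0999 against 11.16 ± 0.251 log2 units). Of 21448 probe sets, 3784 rose and 2515 fell, 29.4% in all, and 2662 risen and 706 fallen ones changed at least 2-fold. The 706 were 1167 without control replicate 1 and 1143 under quantile normalization.

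Among the 8 named genes with the largest rises were also ZFAND2A (log2 change 4.53), a proteasome-associated protein induced by arsenite, the AP-1 subunit JUN (4.51) and the chaperones HSPH1 (4.26) and DNAJB4 (4.19). IFRD1 (4.30) and CHAC1, which degrades glutathione (18.4-fold), completed them. The 8 largest falls included IFI27 (-3.32), OAS1 (-3.27) and IFITM1 (-3.23), all interferon-induced, the WNT antagonist DKK1 (-2.76), the linker histone H1-4 (-2.69) and ID1 (-2.36), an inhibitor of helix-loop-helix factors.

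Most NRF2 targets, the antioxidant and detoxification genes that isothiocyanates are known to induce, were higher with sulforaphane. Of 29 measured, 19 rose and 10 did not pass (21 rose and 1 fell adjusted over the list alone; 2 fell without control replicate 2). The median log2 change was 0.94, with an adjusted p of 2.63e-09 in the list test and adjusted p = 0.36 with an estimated correlation. HMOX1, heme oxygenase 1, rose 6.19-fold (8.635 ± 0.165 against 6.006 ± 0.264 log2 units). The glutathione synthesis genes GCLC and GCLM rose by 3.17 and 3.05 log2 units, SRXN1 by 1.99 and the quinone reductase NQO1 by 0.87 (SE 0.212, adjusted p = 0.00893). Control replicate 2 enlarges the rises of GCLM (3.511 there, 5.555 and 4.61 on the other controls) and NQO1 (10.53, against 11.223 and 11.114). Metallothioneins, small metal-binding proteins, fell instead. All 8 measured fell, over all genes and adjusted over the list alone, with a median of -0.91 (list adjusted p = 7.19e-05; adjusted p = 0.36 with an estimated correlation). MT2A fell by 0.83 and MT1H by 1.08, although these near-identical genes may share probes.

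Chaperone and amino acid stress genes rose as groups. Of 18 heat shock chaperones 14 rose, over all genes and adjusted over the list alone. Their median change was 1.82 (list adjusted p = 1.42e-09; adjusted p = 0.36 with an estimated correlation). HSPA1A, whose probes may also read HSPA1B, rose 11.7-fold and DNAJB1 by 3.04 log2 units. Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose in 15 of 23 cases (15 adjusted over the list alone), with a median of 1.61 (list adjusted p = 1.45e-09; adjusted p = 0.173 with an estimated correlation). DDIT3, which encodes CHOP, rose 16.2-fold and the phosphatase subunit PPP1R15A by 3.31 log2 units. Of 21 chaperones and degradation factors of the endoplasmic reticulum (ER), 14 rose (15 rose and 1 fell adjusted over the list alone), with a median of 0.93. This list's adjusted p was 1.18e-06 (adjusted p = 0.36 with an estimated correlation), and HERPUD1 (3.45), SEL1L (2.20) and HSPA5, the chaperone BiP (1.94), were among its risen members. When control replicate 2 was left out, 1 gene each fell of the ATF4 and CHOP, ER, immediate early and p53 lists. Immediate early genes rose in 13 of 17 cases (14 adjusted over the list alone; median 1.59). Their list adjusted p was 1.55e-10 (adjusted p = 0.0745 with an estimated correlation). EGR3 (4.11), FOSB (3.72) and FOS (3.57) were among them.

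Interferon-stimulated genes formed the group that fell furthest by median with all 9 arrays. Of 20 measured, 12 fell and 8 did not pass, over all genes and adjusted over the list alone, with a median of -1.01 (list adjusted p = 1.06e-06; adjusted p = 0.0592 with an estimated correlation; median -1.7, adjusted p = 6.32e-07 without the dimmest probe sets). ISG15, a ubiquitin-like modifier, fell by 2.31 log2 units. Without control replicate 2 the interferon median was -0.972, against -0.979 for metallothioneins. Of 22 replication-dependent histone genes, whose probes may be shared within the family, 9 fell by either adjustment, including H1-2 (-1.46) and H4C12 (-1.17). Their median was -0.52 (list adjusted p = 0.000475; adjusted p = 0.446 with an estimated correlation), which lay at percentile 9.93 of random lists matched on gene span and signal level.

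Cell cycle genes rose in part with sulforaphane. Of 30 G2/M genes 15 rose (15 rose and 1 fell adjusted over the list alone; median 0.76, list adjusted p = 0.000621; adjusted p = 0.624 with an estimated correlation). The kinetochore protein gene CENPF rose by 2.05 and the motor protein gene KIF11 by 1.66 log2 units. CCNB1 did not pass (0.16, SE 0.312, adjusted p = 0.723) and turned to -0.28 without control replicate 2 (adjusted p = 0.185). The proliferation marker MKI67 rose by 1.11 (adjusted p = 0.0151), a call lost without sulforaphane replicate 1 (1.09, adjusted p = 0.0542), and by 0.68 without control replicate 2. Of 29 G1/S and replication genes 13 rose (14 adjusted over the list alone), among them CDC6 (2.16) and CCNE2 (1.80). Their median was 0.54 (list adjusted p = 0.000909; adjusted p = 0.624 with an estimated correlation). Without control replicate 2 the G2/M median was 0.44 (adjusted p = 0.0349) and the G1/S median 0.35, no longer passing (adjusted p = 0.0558; 0.29 under quantile normalization), and 6 G2/M genes and 4 G1/S genes then fell beside the 15 and 13 that rose.

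Growth arrest and death genes moved in part. Of 19 p53 targets 9 rose (10 adjusted over the list alone), with a median of 0.57 (list adjusted p = 0.000739; adjusted p = 0.36 with an estimated correlation). That median lay at percentile 96.5 of the matched random lists. RRM2B (2.78), the death receptor gene TNFRSF10B (2.22) and GADD45A (1.37) rose, and the cyclin-dependent kinase inhibitor CDKN1A rose 2.41-fold (adjusted p = 0.00541). CDKN1A stood at 7.836 log2 units on control replicate 2, against 9.091 and 8.965 on control replicates 1 and 3. That array therefore enlarges the fold. Of 18 pro-apoptotic genes 7 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.59, percentile 97.0). This list's adjusted p was 0.0305, adjusted p = 0.36 with an estimated correlation, and 0.0594 without control replicate 2 (median 0.32, 8 risen and 3 fallen). It was 0.0766 under quantile normalization and 0.138 without the dimmest probe sets. PMAIP1 (2.38) and APAF1 (1.40) were among the risen. Of 9 anti-apoptotic genes 4 rose and 1 fell by either adjustment, including MCL1 (2.23) and BIRC2 (1.64), and the list did not pass (median 0.57, adjusted p = 0.255; 0.37 and 0.567 without control replicate 2, with 3 fallen).

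Protein turnover lists passed weakly. Of 26 proteasome subunits 10 rose, such as PSMC6 (1.65) and PSMD1 (1.53), and 2 fell, by either adjustment (list adjusted p = 0.0335; adjusted p = 0.699 with an estimated correlation). Their median of 0.27 lay at percentile 53.3 of the matched lists. It was 0.08 under quantile normalization (adjusted p = 0.321), and the list did not pass without the dimmest probe sets (0.163). The median turned to -0.08 without control replicate 2 (adjusted p = 0.773), with 10 risen and 8 fallen, and was 0.52 and 0.43 without control replicates 1 and 3. Of 21 autophagy and lysosome genes 8 rose by either adjustment, including MAP1LC3B (2.53), an autophagosome marker, and SQSTM1 (1.40). The median was 0.23, at percentile 49.2 of the matched lists (list adjusted p = 0.015; adjusted p = 0.626 with an estimated correlation). It was 0.04 without control replicate 2 (adjusted p = 0.199), with 8 risen and 4 fallen, 0.51 and 0.42 without control replicates 1 and 3, 0.11 under quantile normalization (adjusted p = 0.11) and 0.37 without the dimmest probe sets (adjusted p = 0.059).

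Intestinal and epithelial genes gave mixed values. Of 20 intestinal differentiation genes 4 fell and 1 rose by either adjustment, with AQP8 at -1.05, the microvillus gene VIL1 at -0.96 and the carbonic anhydrase CA2 at 0.84 (a call lost under quantile normalization, 0.56, adjusted p = 0.136). The list median was -0.50 (adjusted p = 0.0197; adjusted p = 0.624 with an estimated correlation), and without control replicate 2 it was -0.27 (adjusted p = 0.176). Of 17 epithelial junction and keratin genes 7 rose and 2 fell by either adjustment, including OCLN (2.34) and KRT19 (-0.93). This list did not pass (median 0.42, adjusted p = 0.127) but did without control replicate 1 (adjusted p = 0.0457), and its median was 0.15 without control replicate 2 (adjusted p = 0.577, with 6 risen and 4 fallen) and under quantile normalization (adjusted p = 0.375). Of 18 epithelial-mesenchymal transition genes 6 rose and 2 fell (6 and 4 adjusted over the list alone), with CCN1 at 2.35 and SNAI1 at 1.88. Its median of -0.02 and mean of 0.34 differ in sign (list test upward, adjusted p = 0.354), and the median was positive without control replicate 1 (0.05) or 3 (0.06), without sulforaphane replicate 1 (0.07) or 3 (0.002) and without the dimmest probe sets (0.11). It was -0.03 without control replicate 2 (6 risen and 5 fallen), -0.10 without sulforaphane replicate 2 and -0.13 under quantile normalization.

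Several metabolic and signalling lists did not pass with all 9 arrays. Of 21 oxidative phosphorylation genes 4 fell by either adjustment, such as CYC1 (-1.20), with a median of -0.27 (adjusted p = 0.0701). That became 15 fallen and a median of -0.55 without control replicate 2 (adjusted p = 1.52e-05; adjusted p = 0.0295 with an estimated correlation). Of 23 glycolysis and hypoxia genes 4 rose, including ADM (2.17), and 3 fell, including ALDOC (-1.37), by either adjustment (median -0.35, adjusted p = 0.265). Leaving out control replicate 2 gave 14 fallen and a median of -0.57 (adjusted p = 0.00509; adjusted p = 0.0807 with an estimated correlation). Of 11 tubulins 1 fell by either adjustment, TUBB4A (-1.02), with a list median of -0.35 (adjusted p = 0.0701). In the fit without control replicate 2, 8 of these related genes fell (list adjusted p = 0.0034; adjusted p = 0.111 with an estimated correlation), and TUBB2A moved from -0.41 (adjusted p = 0.102) to -0.48 (adjusted p = 0.00953). Quantile normalization also brought these 3 lists past the threshold (adjusted p = 0.00182, 0.0475 and 0.0121), and the first also passed without the dimmest probe sets (0.0419). The oxidative phosphorylation median was -0.12 without control replicate 1 (adjusted p = 0.407) and the glycolysis median -0.21 without control replicate 3 (adjusted p = 0.583).

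Of 18 WNT targets 3 rose and 6 fell by either adjustment, with AXIN2 at 1.01 and APCDD1 at -0.96 (median -0.39, adjusted p = 0.123). Of 17 cholesterol genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), with IDI1 at 2.02 and MVK at -0.91. Their median of -0.06 and downward test (adjusted p = 0.956) differ in sign from the mean of 0.11, and the median was 0.13 and 0.10 without control replicates 1 and 3. Leaving out control replicate 2 took it to -0.39 (adjusted p = 0.529), with 5 risen and 9 fallen, and quantile normalization to -0.29. Of 18 NF-kB and inflammatory genes 3 rose (1 adjusted over the list alone), including CXCL8 (1.33). The median of -0.21 differs in sign from the mean of 0.05 and the upward test (adjusted p = 0.852), and was -0.03 without control replicate 2 (adjusted p = 0.773), with 1 risen and 2 fallen, and -0.12 without sulforaphane replicate 3. Of 17 ribosome biogenesis genes 5 rose, such as NOP58 (3.46), and 3 fell by either adjustment (median 0.31, adjusted p = 0.152). That median was 0.009 without control replicate 2 (adjusted p = 0.673), and 0.49 and 0.58 without control replicates 1 and 3. Among 14 genes of the aryl hydrocarbon receptor and xenobiotic metabolism TIPARP rose (1.99) and 1 fell (1 and 0 adjusted over the list alone; median -0.28, adjusted p = 0.607; -0.06 and 0.962 without control replicate 2, with 2 fallen).

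Markers of other cell types were measured as a check of the culture. Of 9 fibroblast markers 1 fell (median -0.29, adjusted p = 0.354) and of 10 leukocyte markers 1 fell (median -0.43, adjusted p = 0.127). Of 9 endothelial markers 2 fell (median -0.40, adjusted p = 0.0639). These counts are the same adjusted over the list alone. Without control replicate 1 the leukocyte and endothelial lists passed (adjusted p = 0.0388 and 0.0332), and the endothelial list also without control replicate 3 (adjusted p = 0.0241). Without control replicate 2 the medians were -0.01 for fibroblast (adjusted p = 0.88), -0.15 for leukocyte (0.572) and -0.10 for endothelial markers (0.529), and the fibroblast median was -0.55 without control replicate 3 (adjusted p = 0.17).

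The direction of change followed gene span, the distance between the ends of the annotated gene, across 17683 named genes (Spearman's rho 0.322 with the log2 change; genes are not independent replicates). In the fifth of genes with the shortest spans 4.35% rose and 19.7% fell with sulforaphane, and in the fifth with the longest 29.0% rose and 5.99% fell. Of all probe sets 44.0% had no overlap between the 3 sulforaphane and the 3 control values, against 10% by chance. The count of 6299 changed probe sets was 3940 without sulforaphane replicate 2 and 3938 without replicate 3. In the absence of control replicate 2, 4097 rose and 3825 fell, and with quantile normalization as well 3945 rose and 4411 fell, so the risen share went from 60.1% to 51.7% and 47.2%. Array weights gave 5415 risen and 6357 fallen.

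**Figure D2:**
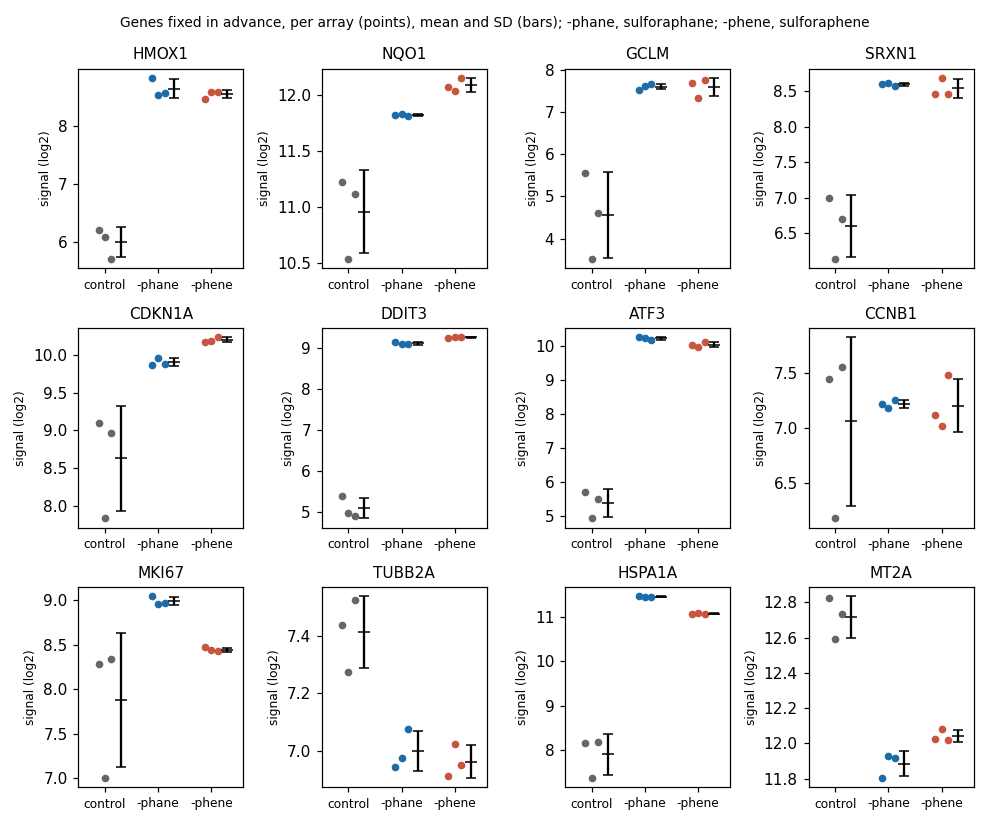
Log2 signal of the 12 genes named in advance, with 1 point per array and bars for the mean and SD of each group. ATF3, DDIT3, HMOX1, GCLM and HSPA1A lie higher on all treated arrays than on control arrays, whereas CCNB1 overlaps (control 7.06 ± 0.763, sulforaphane 7.22 ± 0.0367, mean ± SD).

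The second comparison put the same question for sulforaphene. SLC7A11 showed the largest rise, 29.1-fold, from 5.738 ± 0.109 to 10.6 ± 0.0212 log2 units (mean ± SD, n = 3 each, limma adjusted p = 2.55e-08). ATF3 rose 25.3-fold, DDIT3 17.9-fold and HERPUD1, a component of ER-associated degradation, 14.7-fold (log2 change 3.88, SE 0.256). IFI6 again fell furthest and was 10.9-fold lower (7.712 ± 0.192 against 11.16 ± 0.251 log2 units). In all 4217 probe sets rose and 3304 fell, 35.1% of those tested, of which 2966 and 847 changed at least 2-fold. The 847 were 1690 without control replicate 1, 1401 without control replicate 3 and 1304 under quantile normalization.

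CHAC1 (4.17), JUN (4.08), IFRD1 (3.97), ZFAND2A (3.97) and HSPH1 (3.89) were the other genes among the 8 largest rises. Falls included IFI27 (-3.27), IFITM1 (-2.87), OAS1 (-2.59), IFIT1 (-2.33) and DKK1 (-2.01). The probe set named for HBA2, an alpha globin gene with the near-identical copy HBA1, fell by 2.08 and is uncertain for that reason.

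Of 29 NRF2 targets 20 rose and 9 did not pass (21 rose and 1 fell adjusted over the list alone; 2 fell without control replicate 2), with a median of 1.14 (list adjusted p = 4.55e-09; adjusted p = 0.332 with an estimated correlation). GCLC rose by 3.48, GCLM by 3.04, HMOX1 by 2.54, SRXN1 by 1.93 and NQO1 by 1.14 log2 units (SE 0.212, adjusted p = 0.00166). The low GCLM and NQO1 signals of control replicate 2 enlarge these rises as well. Of 8 metallothioneins 7 fell (8 adjusted over the list alone), including MT1H (-1.14) and MT2A (-0.67), with a median of -0.76 (list adjusted p = 0.00076; adjusted p = 0.332 with an estimated correlation). Heat shock chaperones rose in 13 of 18 cases by either adjustment, with HSPA1A up 8.95-fold and a median of 1.65 (list adjusted p = 2.08e-08; adjusted p = 0.397 with an estimated correlation). ATF4 and CHOP targets rose in 16 of 23 cases (17 adjusted over the list alone; 1 fell without control replicate 2), with PPP1R15A at 2.89. Their median was 1.64 (list adjusted p = 4.37e-09; adjusted p = 0.191 with an estimated correlation).

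The ER list was the one with the lowest p. Of 21 ER chaperones and degradation factors 17 rose by either adjustment, with a median of 1.39 (list adjusted p = 8.3e-10; adjusted p = 0.332 with an estimated correlation). SEL1L, part of the ubiquitin ligase complex that clears misfolded ER proteins, rose 8.24-fold, DNAJC3 by 2.85 and HSPA5 by 2.38 log2 units. Immediate early genes rose in 13 of 17 cases by either adjustment, with EGR3 at 3.45, FOSB at 3.21 and the phosphatase gene DUSP1 at 2.94 (median 1.62, list adjusted p = 4.37e-09; adjusted p = 0.119 with an estimated correlation). Of 20 interferon-stimulated genes 11 fell (13 adjusted over the list alone; median -0.97, list adjusted p = 1.02e-05; adjusted p = 0.095 with an estimated correlation; median -1.79, adjusted p = 1.22e-06 without the dimmest probe sets).

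Of 19 p53 targets 11 rose (12 adjusted over the list alone), with a median of 1.05 (list adjusted p = 1.69e-05; adjusted p = 0.332 with an estimated correlation). RRM2B rose by 3.14, TNFRSF10B by 2.59, MDM2, the ubiquitin ligase that degrades p53, by 2.31 and CDKN1A by 1.57 log2 units. The low CDKN1A signal of control replicate 2 enlarges the CDKN1A rise here too. Of 18 pro-apoptotic genes 10 rose and 4 fell by either adjustment, with PMAIP1 at 1.98 and FAS at 0.95 (median 0.74). This list's adjusted p was 0.0309, adjusted p = 0.404 with an estimated correlation, and 0.0588 without control replicate 2. It was 0.109 under quantile normalization and 0.17 without the dimmest probe sets. Of 9 anti-apoptotic genes 3 rose by either adjustment, MCL1 (1.95), BIRC2 (1.73) and CFLAR (1.06), and the list did not pass (median 0.64, adjusted p = 0.111; 0.42 and 0.106 without control replicate 1, 0.35 and 0.298 under quantile normalization). In the fit without control replicate 2, 4 of them rose and 2 fell.

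Of 30 G2/M genes 10 rose and 1 fell by either adjustment, with CENPF at 1.81, KIF23 at 1.12 and ECT2 at 1.19 (list adjusted p = 0.0312; adjusted p = 0.693 with an estimated correlation). The median of 0.45 lay at percentile 87.2 of the span-matched lists. Leaving out control replicate 2 took it to 0.19 (adjusted p = 0.422), with 10 risen and 7 fallen, and without sulforaphene replicate 3 it was 0.46 (adjusted p = 0.058). Under quantile normalization it was 0.22 (adjusted p = 0.301), and the list did not pass without the dimmest probe sets (0.211). MKI67 (0.57, SE 0.300, adjusted p = 0.155) and CCNB1 (0.14, SE 0.312, adjusted p = 0.742) did not pass, and were at 0.13 and -0.30 without control replicate 2. Of 29 G1/S and replication genes 7 rose and 3 fell (9 and 3 adjusted over the list alone), with CDC6 at 1.76 and the thymidine kinase gene TK1 at -1.01. This list did not pass (median 0.24, adjusted p = 0.12) but did without control replicate 3 (0.43, adjusted p = 0.0258). Its median was 0.04 without control replicate 2 (adjusted p = 0.866), with 7 risen and 7 fallen, and turned to -0.02 under quantile normalization (adjusted p = 0.625). Of 22 histone genes 8 fell by either adjustment, with H1-4 at -1.58 and H4C3 at -0.93. Their median of -0.51 lay at percentile 28.7 of the matched lists (list adjusted p = 0.00266; adjusted p = 0.52 with an estimated correlation), and 17 fell without control replicate 2.

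Of 26 proteasome subunits 10 rose, such as PSMC6 (1.57), and 1 fell by either adjustment (list adjusted p = 0.0207; adjusted p = 0.693 with an estimated correlation). Their median of 0.33, at percentile 49.8 of the matched lists, was 0.03 under quantile normalization (adjusted p = 0.386), and the list did not pass without the dimmest probe sets (0.147). It turned to -0.03 without control replicate 2 (adjusted p = 0.423), with 10 risen and 7 fallen, and was 0.55 and 0.51 without control replicates 1 and 3. Of 21 autophagy and lysosome genes 9 rose by either adjustment, such as MAP1LC3B (2.37), with a median of 0.54 at percentile 82.2 (list adjusted p = 0.00879; adjusted p = 0.627 with an estimated correlation, and 0.078 without control replicate 2, at a median of 0.28 with 3 fallen). Under quantile normalization the median was 0.27 (adjusted p = 0.0973). Of 17 ribosome biogenesis genes 9 rose and 2 fell by either adjustment, with NOP58 at 3.44 and DDX21 at 2.52 (median 0.75, list adjusted p = 0.0309; adjusted p = 0.627 with an estimated correlation). This list's median was 0.43 without control replicate 2 (adjusted p = 0.102) and 0.47 under quantile normalization (0.152), and it did not pass without the dimmest probe sets (0.17).

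Of 11 tubulins 2 fell by either adjustment, TUBB6 (-1.18) and TUBB4A (-1.01), with a median of -0.46 at percentile 10.8 of the matched lists (list adjusted p = 0.0232; adjusted p = 0.616 with an estimated correlation). The list was lost without control replicate 1 (adjusted p = 0.0621) or 3 (0.0595), while 9 fell without control replicate 2 (list adjusted p = 0.000182; adjusted p = 0.0659 with an estimated correlation). Under quantile normalization the median was -0.71 (adjusted p = 0.000812). TUBB2A went from -0.45 (adjusted p = 0.0686) to -0.52 (adjusted p = 0.00642) without control replicate 2. Of 21 oxidative phosphorylation genes 5 fell by either adjustment, such as NDUFV1 (-1.03), and the list did not pass (median -0.13, adjusted p = 0.287). In the fit without control replicate 2, 12 fell and the median was -0.51 (adjusted p = 0.00143; adjusted p = 0.0659 with an estimated correlation), and without control replicate 1 it turned to 0.04 (adjusted p = 0.869). It was -0.03 without control replicate 3 (adjusted p = 0.707). Of 23 glycolysis and hypoxia genes 3 rose and 3 fell by either adjustment, with VEGFA at 1.61 and ALDOC at -1.30 (median -0.27, adjusted p = 0.375). The fallen were 15 without control replicate 2 (median -0.52, list adjusted p = 0.0141; adjusted p = 0.0946 with an estimated correlation). Quantile normalization also brought the last 2 lists past the threshold (adjusted p = 0.00847 and 0.0428).

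Of 20 intestinal differentiation genes 5 fell by either adjustment, including AQP8 (-0.96), with a median of -0.41 at percentile 27.0 (list adjusted p = 0.0309; adjusted p = 0.627 with an estimated correlation). The fallen were 3 without control replicate 2 (list adjusted p = 0.269), and the list did not pass under quantile normalization (0.0948). Of 17 epithelial junction and keratin genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with OCLN at 2.28 and ESRP1 at 1.65. The list did not pass (median 0.63, adjusted p = 0.0538) but did without control replicate 1 (adjusted p = 0.0209) or 3 (0.024), and its median was 0.37 without control replicate 2 (adjusted p = 0.268, with 5 fallen) and 0.29 under quantile normalization (adjusted p = 0.301). Of 18 epithelial-mesenchymal transition genes 4 rose and 3 fell by either adjustment, with CCN1 at 1.93 and ZEB2 at -0.91. The median of -0.10 and mean of 0.17 differ in sign (test upward, adjusted p = 0.707), and the median was 0.01 without control replicate 1 and 0.001 without the dimmest probe sets. It was -0.06 without control replicate 2 (6 fallen) and -0.008 without control replicate 3. Of 18 WNT targets 3 rose and 6 fell (3 and 7 adjusted over the list alone; median -0.28, adjusted p = 0.161; -0.42 without sulforaphene replicate 1, -0.48 under quantile normalization), with RNF43 at 1.26 and APCDD1 at -1.03.

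Of 17 cholesterol genes 5 rose and 7 fell (6 and 7 adjusted over the list alone), with IDI1 at 1.62. The median of -0.26 and the downward test (adjusted p = 0.853) differ in sign from the mean of 0.08. The fit without control replicate 2 gave a median of -0.425 (adjusted p = 0.422), with 6 risen and 9 fallen, and quantile normalization one of -0.49. Of 18 NF-kB and inflammatory genes 5 rose (4 adjusted over the list alone), including the chemokine genes CXCL8 (2.13) and CCL20 (0.96). The median of -0.10 differs in sign from the mean of 0.16 and the upward test (adjusted p = 0.517), and was 0.04 without control replicate 2 (1 fallen) and 0.0006 without replicate 3. It was -0.03 without sulforaphene replicate 1 or 3, and -0.28 without the dimmest probe sets. Of 14 xenobiotic metabolism genes 2 rose and 2 fell by either adjustment, with TIPARP at 1.78 (median -0.35, adjusted p = 0.375).

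Of the markers of other cell types, 2 of 9 fibroblast genes fell (0 adjusted over the list alone; median -0.40, adjusted p = 0.204). Of 10 leukocyte genes 3 fell by either adjustment, including PTPRC (-1.08), with a median of -0.64 (list adjusted p = 0.0417; adjusted p = 0.558 with an estimated correlation). This list did not pass without control replicate 2 (median -0.31, adjusted p = 0.224) or sulforaphene replicate 2 (0.0755), nor under quantile normalization (0.116). Of 9 endothelial genes 5 fell (6 adjusted over the list alone), including EGFL7 (-1.28), with a median of -0.69 (list adjusted p = 0.0106; adjusted p = 0.52 with an estimated correlation, and 0.0821 without control replicate 2).

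Span and direction went together here as well (Spearman's rho 0.339 across 17683 genes), with 4.52% risen and 27.5% fallen in the fifth of shortest span and 33.3% risen and 7.72% fallen in that of longest span. Sulforaphene and control values did not overlap for 47.6% of probe sets, against 10% by chance. The count of 7521 changed probe sets was 4548 without sulforaphene replicate 3. Without control replicate 2, 4424 rose and 4287 fell, and with quantile normalization as well 4117 rose and 4651 fell. Array weights gave 5142 risen and 6243 fallen.

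**Figure D3:**
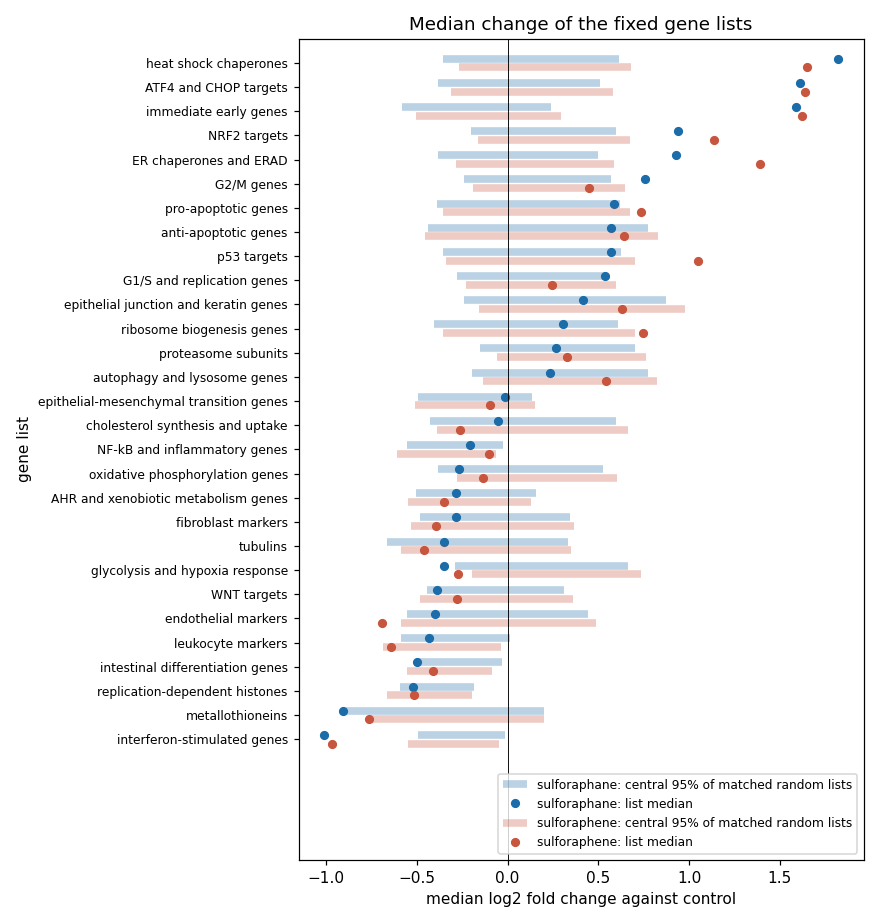
Median log2 change of each of the 29 gene lists against control (points: blue sulforaphane, red sulforaphene), with bars for the central 95% of random lists matched on gene span and signal level. Heat shock, ATF4 and CHOP, immediate early, NRF2 and ER lists lie above their bars, and the interferon list below them at -1.01 and -0.97, while proteasome (0.27 and 0.33) and autophagy (0.23 and 0.54) medians lie inside theirs.

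The responses to the 2 compounds were close to each other. Of the probe sets that rose with sulforaphane 92.1% also rose with sulforaphene, and of those that fell 70.7% also fell. In numbers, 3486 rose with both and 1779 fell with both, against 744 and 387.4 for independent lists of those lengths, and limma called 0 in opposite directions. Across genes the log2 changes correlated at r = 0.943, with 89.2% of the same sign. Unchanged groups simulated against the same controls gave r = 0.845 and 79.7%. The covariance was 0.578, against 0.0841 in that simulation, a difference of 0.494. Without control replicate 2, r was 0.923 and the covariance 0.431. Both comparisons share the 3 controls, which are too few to split into separate sets, so part of the excess may come from them.

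**Figure D4:**
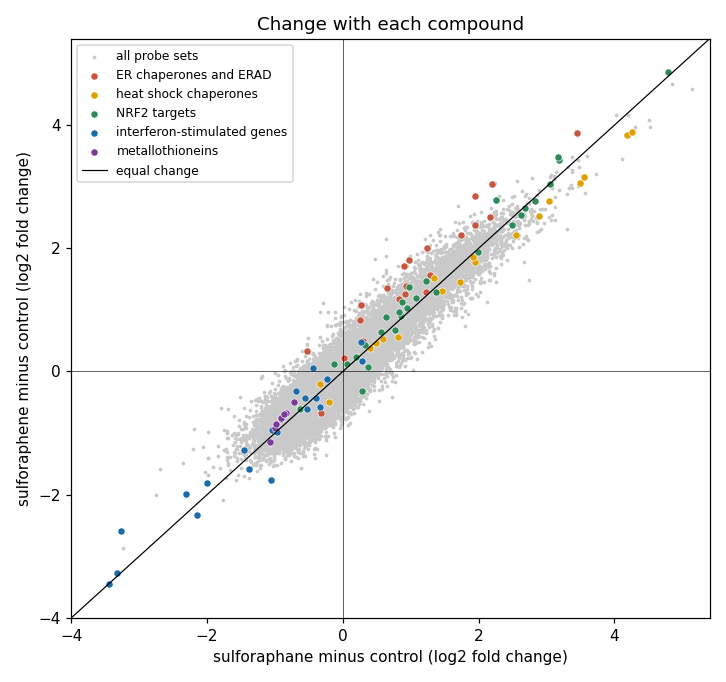
Log2 change against control with sulforaphane (horizontal axis) and with sulforaphene (vertical axis), 1 point per probe set, with 5 gene lists in colour and a line of equal change. Points crowd along the line (r = 0.943, against 0.845 for simulated unchanged groups with the same controls).

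The third comparison set sulforaphene directly against sulforaphane at the same dose and time, which asks whether the double bond in the side chain goes with a different response. ER chaperones were the group that differed most. Of 21 measured, 20 had a higher mean with sulforaphene, and in 17 all 3 sulforaphene arrays lay above all 3 sulforaphane arrays. The median difference was 0.47 log2 units (1.38-fold). DNAJC3, an ER co-chaperone, stood at 8.55 ± 0.07 with sulforaphene and 7.64 ± 0.10 with sulforaphane (mean ± SD, n = 3 each), a difference of 0.91. Against that, limma with all 9 arrays called 0 single probe sets, with 1021 at an unadjusted p under 0.05 against 1072 expected by chance.

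With all 9 arrays the lowest limma adjusted p was 0.484. It was shared by the chemokine gene CCL20 (difference 1.30, 95% interval 0.83 to 1.77), FSAF1 and OR51I1. FSAF1 and OR51I1 differed by more than CCL20 and were also higher with sulforaphene. The CCL20 mean with sulforaphane was low, at 2.43 log2 units, against lower quartiles of 3.81 to 3.82 on the sulforaphane arrays. The median 95% interval reached 0.524 log2 units to either side. Non-overlapping values of the 2 compounds were found for 5694 probe sets, 26.5% against 10% by chance. Control replicate 2 enters this comparison only through the pooled spread. Without it the median standard error fell from 0.242 to 0.151, and limma called 95 probe sets higher and 31 lower with sulforaphene, 19 of them at least 2-fold. With only the 6 treated arrays 46 were called, 42 of them among those 126.

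The genes fixed in advance gave intervals rather than calls. HMOX1 differed by -0.09 (95% interval -0.53 to 0.34), NQO1 by 0.27 (-0.19 to 0.73), GCLM by -0.01 (-0.84 to 0.82) and SRXN1 by -0.06 (-0.55 to 0.44). DDIT3 differed by 0.14 (-0.27 to 0.56), ATF3 by -0.19 (-0.66 to 0.29), CDKN1A by 0.30 (-0.32 to 0.91) and HSPA1A by -0.38 (-0.88 to 0.11). MKI67 differed by -0.55 (-1.20 to 0.10), CCNB1 by -0.02 (-0.70 to 0.66), MT2A by 0.16 (-0.23 to 0.54) and TUBB2A by -0.04 (-0.43 to 0.35). Adjusted p was 0.999 for each of them, and such a p does not show that the compounds act alike.

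Of the 21 ER genes, 7 were higher with sulforaphene adjusted over the list alone (list adjusted p = 3.44e-13; adjusted p = 0.52 with an estimated correlation). Examples are MANF, a secreted ER stress protein (0.85, 95% interval 0.38 to 1.31), SEL1L (0.84, 0.39 to 1.29) and SDF2L1 (0.86, 0.43 to 1.28). Without control replicate 2, 5 ER genes passed over all genes: SDF2L1 (adjusted p = 0.0352), DNAJC3 (0.0439), PDIA4, HYOU1 and SYVN1. The p53 target list was also higher, with a median of 0.28, 17 of 19 members positive and 2 passing adjusted over the list alone (list adjusted p = 0.000271; adjusted p = 0.656 with an estimated correlation). MDM2 differed by 0.89 (0.45 to 1.33; adjusted p = 0.0352 without control replicate 2) and SESN1, a sestrin, by 0.83 (0.38 to 1.28). Ribosome biogenesis genes had a median of 0.18 with 12 of 17 positive (list adjusted p = 0.0328; adjusted p = 0.793 with an estimated correlation). That call was lost without sulforaphene replicate 2 (adjusted p = 0.0726) or 3 (0.0692) and without sulforaphane replicate 2 (0.0503) or 3 (0.0552). It was also lost under quantile normalization (median 0.10, adjusted p = 0.201) and without the dimmest probe sets (0.0615).

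Cell cycle lists were lower with sulforaphene than with sulforaphane. Of 29 G1/S and replication genes 28 had a lower mean, with a median of -0.27 (list adjusted p = 3.86e-07; adjusted p = 0.793 with an estimated correlation). CCNE2 differed by -0.83 and DTL by -0.70. Of 30 G2/M genes 25 were lower, again with a median of -0.27 (list adjusted p = 0.000271; adjusted p = 0.793 with an estimated correlation), and CENPE, a kinetochore motor gene, differed by -0.73 (-1.18 to -0.28; adjusted p = 0.045 without control replicate 2). Immediate early genes were lower in 13 of 17 cases (median -0.23, list adjusted p = 0.000971; adjusted p = 0.558 with an estimated correlation), with FOS at -0.67 and EGR3 at -0.66. Heat shock chaperones were lower in 16 of 18 cases, with a median of -0.25 and CHORDC1 at -0.45 (list adjusted p = 0.0186; adjusted p = 0.793 with an estimated correlation). This list did not pass without sulforaphene replicate 2 (adjusted p = 0.0726) or sulforaphane replicate 1 (0.0802). In these 4 lists no member passed singly with all 9 arrays, over all genes or adjusted over the list alone.

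Smaller shifts passed for the epithelial-mesenchymal transition list (median -0.13, 14 of 18 lower, adjusted p = 0.0411; adjusted p = 0.52 with an estimated correlation) and the endothelial markers (median -0.18, 8 of 9 lower, adjusted p = 0.0411; adjusted p = 0.793 with an estimated correlation). SNAI2 differed by -0.84 and PECAM1 by -0.57. The first was lost without sulforaphene replicate 1 (adjusted p = 0.147) or 3 (median -0.08, 0.0628), without each sulforaphane replicate (0.0582, 0.0698 and 0.0716) and without control replicate 3 (0.052). The second was lost without sulforaphene replicate 2 (0.124) or 3 (0.208) and without each sulforaphane replicate (0.093, with a median of -0.30, 0.0503 and 0.0538). Quantile normalization (0.123) and leaving out the dimmest probe sets (0.135) ended it too. Medians of the ribosome biogenesis, epithelial-mesenchymal transition and endothelial lists lay at percentiles 96.4, 2.65 and 4.49 of the lists matched on span and level. Differences between the compounds followed span less closely (Spearman's rho 0.109 across genes).

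The other 20 lists did not pass between the compounds with all 9 arrays. Medians were 0.06 for NRF2 targets (adjusted p = 0.393), 0.14 for metallothioneins (0.182), 0.09 for histones (0.23) and 0.14 for anti-apoptotic genes (0.295). They were 0.01 for WNT targets (0.557), -0.02 for cholesterol genes (0.853), 0.06 for glycolysis and hypoxia genes (0.822) and 0.04 for NF-kB and inflammatory genes (0.295). Adjusted over the list alone 1 histone, H1-4 (1.11, 95% interval 0.65 to 1.56), and 1 inflammatory gene, CCL20, were higher and the sterol sensor gene INSIG1 was lower (-0.84, -1.25 to -0.42). These 3 genes also passed over all genes when control replicate 2 was left out (adjusted p = 0.026, 0.0313 and 0.045). Medians were 0.06 for proteasome (0.458), 0.07 for autophagy (0.615), 0.12 for epithelial junction (0.253), 0.07 for interferon (0.445) and 0.08 for intestinal genes (0.817), the last at percentile 97.9 of the lists matched on span and level. Xenobiotic metabolism genes had a median of -0.19 (0.379), at percentile 1.34 of such lists, fibroblast markers -0.10 (0.379) and leukocyte markers -0.11 (0.23; -0.26 and 0.0439 without the dimmest probe sets). Under quantile normalization the medians of NRF2 targets (-0.01), pro-apoptotic genes (-0.03), glycolysis and hypoxia genes (-0.002), proteasome (-0.03) and autophagy genes (-0.005) turned negative. The WNT, cholesterol, pro-apoptotic and autophagy medians turned sign in at least 1 fit without a treated array. Other medians kept their sign but moved over the alternatives. They ran from 0.0893 to 0.155 for metallothioneins, 0.0152 to 0.0982 for histones and 0.0176 to 0.198 for anti-apoptotic genes. For interferon genes the range was 0.00521 to 0.0792 and for fibroblast markers -0.227 to -0.0393. The ATF4 and CHOP list had a median of -0.03, a mean of 0.02 and an upward test (adjusted p = 0.949), and the pro-apoptotic list a median of 0.04, a mean of 0.01 and a downward test (adjusted p = 0.985). Tubulins (median -0.17, adjusted p = 0.182) and oxidative phosphorylation genes (0.13, 0.113) passed without control replicate 2 (adjusted p = 0.0363 and 0.0172; adjusted p = 0.25 and 0.156 with an estimated correlation) and with only the 6 treated arrays (0.0406 and 0.021). Tubulins also passed under quantile normalization (0.00902).

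**Figure D5:**
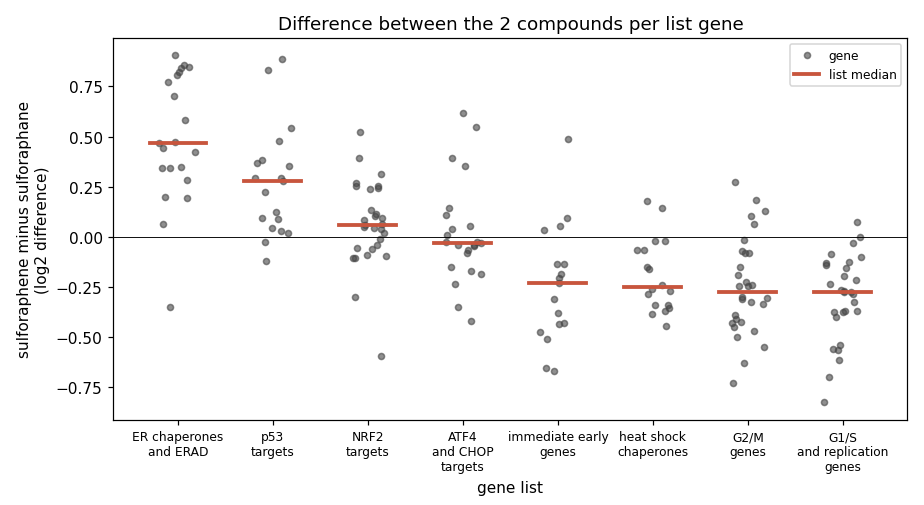
Difference between the compounds (sulforaphene minus sulforaphane, log2) of each measured gene of 8 lists, 1 point per gene with the list median as a bar. ER and p53 medians lie above 0 (0.47 and 0.28), those of NRF2 (0.06) and of ATF4 and CHOP targets (-0.03) near it, and those of immediate early, heat shock, G2/M and G1/S genes below it (-0.23 to -0.27).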

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

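The tests of range and label for control replicate 2, of scaling and of a general response for the ER list, and of control replicate 2 and RNA integrity for gene span were chosen after the result was seen. The random lists matched on span and level, used for the ER list below, were also added after the data were seen.

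A direct test of the difference between the compounds singled out 9 gene lists. ER chaperones and degradation factors were higher with sulforaphene by a median of 0.466 log2 units, p53 targets by 0.28 and ribosome biogenesis genes by 0.178. The G1/S list was lower by a median of -0.274 and the G2/M list by -0.274. Heat shock chaperones had a median of -0.252, immediate early genes -0.232, endothelial markers -0.18 and epithelial-mesenchymal transition genes -0.134. Each passed with the preset correlation. With estimated correlations camera of limma called 0 of the 29 lists (2 at an unadjusted p under 0.05).

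Every comparison allows only 10 splits of its 6 arrays into 3 and 3, too few for a share under 0.05. Each split other than the real one puts arrays of both groups on either side. A group difference then enters the spread within a side, which works against calls of probe sets. Part of it also remains between the sides, so lists can still pass. Counts from these splits therefore do not show what chance alone would give. With sulforaphane the real split gave 6299 changed probe sets (1 of 10 splits as large; highest other 0), 3368 at 2-fold (1; highest other 0) and 15 lists (5; highest other 19). With sulforaphene it gave 7521 (1; highest other 0), 3813 (1; highest other 0) and 18 lists (2; highest other 18). Between the compounds it gave 0 probe sets by limma (10; highest other 0; 1021 at an unadjusted p under 0.05), 0 at 2-fold (10; highest other 0) and 9 lists (1; highest other 2).

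Control replicate 2 stood apart from the other controls. A narrower range alone would keep the ranks, but its highest Spearman's rho with another control was 0.881, below the lowest of the other controls with treated arrays (0.914). A treated sample under a control label is argued against by its place on the axis from the other controls (0) to the treated arrays (1), which was -0.256. RNA of fibroblasts, leukocytes or endothelial cells cannot be told apart, since the highest of 22 markers, NKG7, reached 7.003 log2 units against 5.99 in the other controls, between the bounds set for the test. No other biological explanation was tested, since the design gives none. The gap between genes of long and short span was also lowest on this array, at -1.11 log2 units. The other controls had -0.699 and -0.724. RNA integrity as the reason that this array stands apart was not tested.

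The ER list differed between the compounds. Scaling between arrays as the whole cause is argued against by a median of 0.399 under quantile normalization (adjusted p 1.86e-13 to 6.05e-11 over the alternatives with the preset correlation, 0.52 with an estimated one). Gene span and signal level are argued against by its place at percentile 100 of matched random lists. A stronger response to sulforaphene in general is argued against less firmly, by the heat shock list, which both compounds raised and which had a median difference of -0.252 (-0.278 to -0.193 over the alternatives; adjusted p 0.0186, 5.48e-06 to 0.0802 over the alternatives, over the threshold without sulforaphene replicate 2 or sulforaphane replicate 1 and with an estimated correlation, 0.793). The ATF4 and CHOP targets of the integrated stress response did not pass between the compounds (median -0.0311, camera adjusted p = 0.949). That sulforaphene may engage the chaperone and degradation genes of the ER more than sulforaphane at this dose stays open as a hypothesis, found and tested on the same arrays.

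Genes of longer span rose more often with both compounds. Control replicate 2 as the whole cause is argued against by a rho of at least 0.292 without it, and scaling by a rho of at least 0.33 under quantile normalization. RNA integrity that differs between control and treated samples cannot be told apart from the treatment: the gap between long and short genes was 1 log2 unit higher in treated arrays (-1.11 to -0.699 in controls, 0.12 to 0.26 in treated arrays), and the 2 vary together by design. Span here is the length of the gene in the genome, not of the transcript, so this gap is no direct measure of RNA integrity. An effect of the compounds themselves stays open and was not tested.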

How the results depend on the processing

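The fits without control replicate 2 in the comparison between compounds, the averaged sulforaphane replicates and the settings that join 2 choices were chosen after the data were seen. Of 7073 gene and list values under alternatives, 6644 kept the side of the threshold found with all 9 arrays and, where called, the direction. A turn of sign between 2 values that did not pass was counted as the same call. Of the 6644, 2125 gene and 390 list values belong to the comparison between compounds, where 0 named genes were called with all 9 arrays. Among the named genes, 100 of the 111 called with sulforaphane and 101 of the 119 called with sulforaphene were called in every setting. Between the compounds 61 named genes passed in at least 1 setting.

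The counts of changed probe sets stayed within 1.5-fold under quantile normalization, median centring, the dim filter, the variance prior with trend and the replicate block. With array weights, which give control replicate 2 a weight of 0.0552, they were 11772, 11385 and 1782 (44 at 2-fold between the compounds). With only 6 arrays they were 4974 for sulforaphene and 46 between the compounds (12 at 2-fold). Averaging sulforaphane replicates 2 and 3 gave 3960 for sulforaphane. Quantile normalization without control replicate 2 gave 76 between the compounds (16 at 2-fold). CCNB1 with sulforaphene reversed there, to -0.46 (adjusted p = 0.0314, 0.0314 to 0.993 over its alternatives). Fewer arrays or weights change the residual spread by construction; for the other shifts the cause was not tested.

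Leaving out each replicate gave 3938 to 7922 changed probe sets with sulforaphane (lowest without sulforaphane replicate 3, and 3940 without replicate 2) and 4548 to 8951 with sulforaphene (lowest without sulforaphene replicate 3). Between the compounds the range was 0 to 126, and 0 to 19 at 2-fold, with both highest values without control replicate 2. A group left with 2 arrays borrows the spread of the others. With estimated correlations the passing lists went from 15, 18 and 9 to 0, 0 and 0 by camera of limma (3, 4 and 2 at an unadjusted p under 0.05). Without control replicate 2 they went to 7, 7 and 0 (11, 11 and 7). The size of the correlation alone does not account for the lost calls. With sulforaphane the interferon list had an estimated correlation of 0.0108, near the preset 0.01. Its adjusted p by camera still went from 1.06e-06 to 0.0592 with all 9 arrays. In the fit without control replicate 2 the estimated correlation fell for most lists (heat shock chaperones from 0.622 to 0.0788). It rose for the NF-kB, WNT, epithelial-mesenchymal transition and xenobiotic metabolism lists. Why the correlations moved was not tested. The NRF2, heat shock, ATF4 and CHOP, immediate early, interferon and histone lists passed there with each compound. The oxidative phosphorylation list passed with sulforaphane and the ER list with sulforaphene. With the preset correlation the lists numbered 13 to 18, 12 to 19 and 6 to 11 over the fits without 1 replicate. Pearson's r of the 2 responses was 0.9544 without the dimmest probe sets, 0.9267 under quantile normalization without control replicate 2, and 0.9233 to 0.9547 over the fits without 1 replicate; the cause was not tested.

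Replicate numbers did not pair the arrays: deviations from the group means correlated at -0.119 to 0.14 between arrays of the same number, and 4 of 9 arrays correlated best with their own number. With the number as a block limma called 6162, 7432 and 0 probe sets (without the block 1021 between the compounds at an unadjusted p under 0.05), and 15, 19 and 9 lists passed, the added one being the epithelial junction list with sulforaphene (adjusted p = 0.0374, 0.0209 to 0.301 over its alternatives). Pseudocounts were not run, because the values are logarithms. Background signals are not given in the sources used here, so a limit of detection was not set. In simulated data with 200 shifted probe sets 1-log2 shifts were recovered in 28% to 42% of cases. The Benjamini-Hochberg cutoff depends on how many probe sets change, and 6299 and 7521 were called against control. These shares therefore do not carry over to the comparisons with control. Between the compounds, where 0 were called, changes of that size may be partly missed.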

Other observations

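The gene families below were picked by the shared start of their symbols, a test chosen after the values were seen, as were the genes named from them.

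Of 88 families of at least 20 genes, 20 differed from all other genes in their share of risen or fallen members in both comparisons (Fisher's exact test, Benjamini-Hochberg adjusted; genes of a family are not independent). Of these, 9 had more risen members in both comparisons and 11 had fewer. Among the latter, of 349 olfactory receptor genes named OR, 3 rose and 11 fell with sulforaphane and 3 and 20 with sulforaphene (6 and 22, and 5 and 32, without control replicate 2), and of 83 interleukin and interleukin receptor genes named IL, 1 rose and 9 fell with sulforaphane and 2 and 16 with sulforaphene (2 and 11, and 3 and 13). OR genes had a median level of 2.98 log2 units. Of 36 CEP genes, most of which encode centrosome proteins, 20 rose with sulforaphane and 21 with sulforaphene (adjusted p = 2.08e-05 for each), with CEP128 at 2.65 and 2.06 log2 units. Deubiquitinases of the USP family rose in 26 and 24 of 60 cases (adjusted p = 0.000181 and 0.00504), with USP53 at 3.38 and 3.25. Of 20 nucleoporins of the NUP family 12 and 13 rose (adjusted p = 0.000591 and 0.000376), with NUP153 at 2.78 and 2.52. RNA-binding proteins named RBM rose in 17 of 37 cases with each compound (adjusted p = 0.00132 and 0.00504), with RBM39 at 2.32 and 2.11. Of 492 zinc finger genes named ZNF 135 and 136 rose (adjusted p = 3.71e-05 and 0.00329), with ZNF143 at 2.85 and 2.41.

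Collagen genes were among the 11 families with fewer risen members, at a median span of 154 kb. Of 42 measured, 9 fell and 1 rose with sulforaphane (median -0.44, adjusted p = 0.469 for falls and 0.0152 for fewer rises), and 15 fell with sulforaphene (median -0.53, adjusted p = 0.0309 for falls). COL23A1 fell by 0.86 and 1.29. Their medians lay at percentile 0 of random families matched on span and level in both comparisons. The CEP medians lay at percentiles 100 and 99.9, those of USP at 100 and 99.9, those of ZNF, near 0 in themselves (0.0454 and 0.00219), at 100 in each, those of RBM at 99.8 and 91.6, those of NUP at 92.6 and 95.6, and those of IL at 13 and 30.5, so the NUP and IL shifts and the RBM shift with sulforaphene are within the central 95% of such families. OR medians, at -0.169 and -0.214, lay at percentiles 97.7 and 99.8, high for their short span and low signal. That compounds of this kind may raise centrosome and deubiquitinase transcripts beyond what their span gives is a hypothesis from these 20 families, found and tested on the same arrays. Zinc finger genes were not raised as a family. More of them rose than of other genes, but their medians, though above those of matched families, lay near 0.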
